A study of Mus musculus with 4 samples.

How the data were processed

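The series holds ChIRP-seq of 4T1-TGL cells in 4 libraries, 1 each for the even and the odd Malat1 probe pools, a lacZ probe control and the input, sequenced as 76-nt single reads per the labels. Peaks were called with MACS 1.4.4 at a p threshold of 1e-05, per the file headers, on 1 merged treatment against the input. Which libraries were merged, and how, is not given in the sources used here, nor is the aligner. The builds mm10 and GRCm38 come from the submitters' processing notes. Per the file headers, the tag size was 25 bp against the 76-nt reads of the labels, the fragment size was 53 bp, the band width was 200 bp, at most 1 tag was kept per position, the effective genome size was 2.7 Gb and the local background was taken over 1 and 10 kb. The input had 58.8 times as many tags as the treatment after duplicate removal, so the treatment depth sets the precision of every peak.

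The deposited peak table gives the count of treatment tags in each peak, not normalized. It gives 10 times the −log10 of the caller's p-value, deposited as the authors computed it and called the p-score here. The deposited fold enrichment is the ratio of tags at the summit to the local background from the scaled input. The deposited false discovery rate, in percent, is 0 in every peak, so peaks were ranked by the p-score where a q-value had been planned. The deposited summit list gives the signal height at each summit, a whole number of overlapping tags of up to 22. These scores are the authors' values and served only to describe, rank and filter peaks within this list. No column belonged to a single library, and the number of per-sample columns left unused was 0.

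The local background of each peak was recovered as height divided by fold and expressed relative to its floor of 0.0167 tags, the genome-wide expectation that the header's values also give to 3 digits. Because the caller takes the larger of the genome-wide and local values, this measure cannot go below 1 and is biased upward. Gene spans came from a RefSeq gene table of GRCm38, the same build, with 49943 genes on the chromosomes used, of which 21887 are protein-coding and 12727 lncRNA. The table gives spans without strand, transcription start, exons or sequence. The planned promoter, exon and intron shares were therefore replaced by the share of summits within 3 kb of either gene end and the share in gene interiors. List tests used the gene and 5 kb on either side in place of 5 kb upstream, and both gene ends in place of promoters. Placement matched on GC content was not run. Chromosome lengths were taken from the first to the last gene or summit, and gaps were not removed.

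Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Chromosomes were tested with exact binomial tests against their share of length. Shares in and near genes were set against 1000 random placements within chromosomes. Each of 26 gene lists, fixed before the data were examined, was compared with lists drawn from protein-coding genes of the same length (20 bins) by an exact stratified permutation distribution. This draw treats members as independent, although genes of a family often lie side by side and can share a summit. The noncoding list was drawn from lncRNA genes, a departure from the plan. All tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Named genes followed a rule fixed before the data were examined: Malat1 and Neat1, the 12 genes with the highest fold at a gene end, the 8 with the most summits and the 8 with the most per kb among genes of at least 10 kb, the up to 4 members of each list with the highest p-score, every Wnt ligand and clade B serpin with a peak, and the 5 highest peaks by fold and by p-score. Meox1, Sost and Dusp3, and the genes tested against their flanks, were named after their values were seen. Peaks on the Y chromosome, the mitochondrial genome and other sequences entered no chromosome test.

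Comparisons of genes of at least 10 kb with their flanks of 500 kb, the blocks on chromosome 11 and the profile around gene ends were added after the data were examined. Blocks were runs of 100-kb bins with at least 20 peaks and a median background of at least 10. Other settings listed before the data were examined were stricter peak sets, merging of peaks within 1 kb, any-base overlap, other windows and other matching, of which that on local density used 5 length bins and 4 density bins. Tests were tried on simulated summits. For the chromosome comparison, 18 of 20 intervals held the planted fold. For the gene-end share, 99.7% of the planted rise was recovered over 77713 summits. For the list test over 21887 genes, 3% of random lists of 25 genes had p under 0.05. These genes were drawn at random and the simulated summits were spread evenly. The value therefore does not give the error rate for families of neighbouring genes on clustered summits. For the comparison of genes with their flanks, 90% of 200 planted genes with 3 times the density of their flanks and at least 10 summits expected were called among 13890, but 587 of these genes reach that expectation. Of 200 planted genes with 1 to 3 summits expected, 6% were called, so the test has little power for most genes.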

Results

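Malat1 is a long nuclear-retained noncoding RNA of nuclear speckles, and the series asked which chromatin it touches in 4T1-TGL cells, a mouse breast cancer line of BALB/c origin. In ChIRP-seq, biotin-labelled oligonucleotides against an RNA pull down the chromatin bound to it, and the recovered DNA is sequenced. The labels name 4 libraries, 1 each of the Malat1 even probe pool, the Malat1 odd probe pool, a lacZ probe control and the input. All 4 titles carry the label WT, and the input is titled as that of the even pool. The processed files hold a single merged list of 77823 peaks with no column for any library, so there was no replicate, no spread between replicates and no comparison of the probe pools. The header of the list names an input control and no lacZ library, so no lacZ background could be set beside these peaks. The merged treatment had 988411 tags, of which 851227 remained after duplicate removal, against 52861677 and 50030325 for the input. Peaks held 665028 tags, which is 78.1% of the treatment tags, in 13.4 Mb of sequence. Most peaks were small, with a median length of 135 bp and a median of 5 tags. A total of 28933 peaks (37.2%) held 3 tags, a count whose exact 95% Poisson interval runs from 0.619 to 8.77 if tags are independent counts. The lengths of these peaks, given at the end, leave that independence in doubt. The authors' fold enrichment over input had a median of 133 and ranged from 6.66 to 1317. It is the height at the summit over the background, and heights stop at 22, a value that 103 peaks share, so the highest folds are saturated and are ordered mostly by their background. Coordinates are 1-based on GRCm38 (mm10), and tests on peaks cover counting error within this list only.

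The Malat1 gene itself carried the longest peak with the most tags in the list. This peak spanned chromosome 19 from 5795447 to 5802752 (7306 bp) and covered 100% of the annotated Malat1 gene (5795690 to 5802672), starting 243 bp before it and ending 80 bp after it. It held 2818 tags, or 0.331% of the treatment tags. The peak with the next most tags held 1534 and lay on the mitochondrial genome, and the next on the nuclear chromosomes held 466. The authors' fold enrichment of 904, exceeded by 96 others, is at this ceiling of height and does not rank the Malat1 peak. Neat1, the neighbouring noncoding RNA that scaffolds paraspeckles (chromosome 19, 5824708 to 5845480), had 1 peak within its span, at 5829947 to 5830154, with 14 tags and a fold enrichment of 256. Within 100 kb of Malat1 there were 7 summits in all, the Malat1 peak included.

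**Figure D1:**
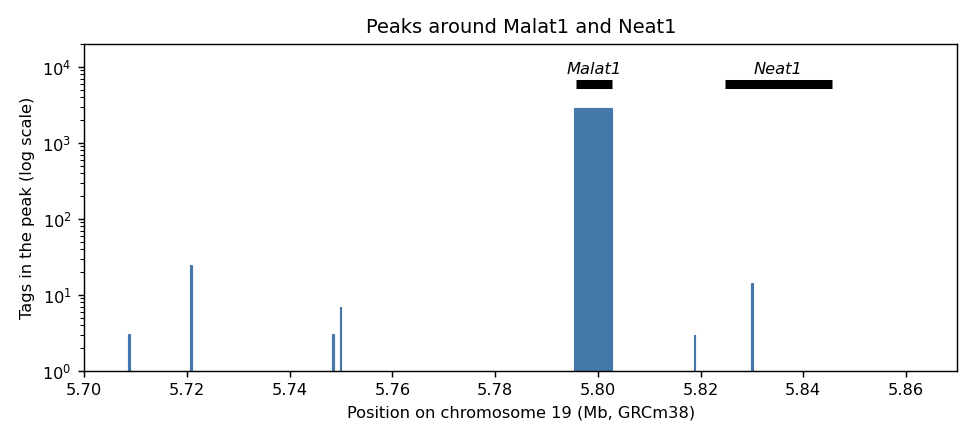
Tags in each peak (vertical log axis) against position on chromosome 19 in Mb (GRCm38), with black bars for the Malat1 and Neat1 genes. The Malat1 peak holds 2818 tags across the whole gene, and the other peaks shown hold 24 or fewer.

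Peaks were spread unevenly over the chromosomes. Chromosome 15 had 61.3 peaks per Mb, 2.06 times the number its length predicts (95% Wilson interval 2.01 to 2.11), against 29.7 over all 20 chromosomes. Chromosome 9 had 45.2 per Mb (1.52 times), chromosome 11 had 42.4 (1.43 times) and chromosome 2 had 39.5 (1.33 times). The X chromosome had 4.01 peaks per Mb, 0.135 times its length share (0.125 to 0.145), and chromosome 14 was lowest among the autosomes with 19.6 per Mb (0.658 times). In exact binomial tests, two-sided and Benjamini-Hochberg adjusted, 17 of the 20 chromosomes passed, 9 with more peaks and 8 with fewer. The local input background, recovered from the authors' height and fold of each peak and given as a multiple of the genome average, also differed between chromosomes. Its median was 2.37 at the peaks of chromosome 15 and 1.73 on chromosome 9, while 91.8% of the X-chromosome peaks lay at the floor of 1. Over the 19 autosomes, peak density and median background had a Pearson r of 0.942 and a Spearman rho of 0.90, each with p = 1e-05, the smallest that 100000 permutations could give. Without chromosomes 15 and 9, the 2 farthest from the median background, r was 0.841. Over 2437 windows of 1 Mb with 5 or more peaks the rho was 0.703, and within single autosomes it ranged from 0.460 to 0.835. Windows are not independent replicates.

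**Figure D2:**
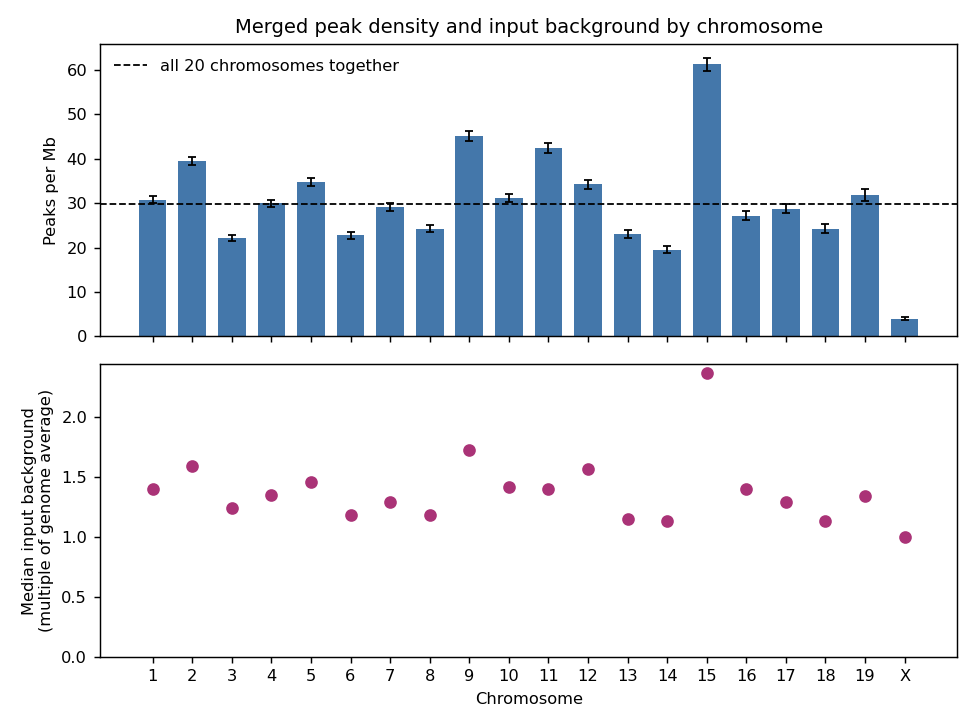
Peaks per Mb with 95% Wilson intervals (upper panel, dashed line at the value of all 20 chromosomes together) and median input background at the peaks as a multiple of the genome average (lower panel), by chromosome. Chromosome 15 is highest in both panels, at 61.3 peaks per Mb and 2.37, and X is lowest, at 4.01 and 1.

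Wnt9b and Wnt3, neighbouring genes of secreted Wnt ligands, lay in the densest part of the list. Wnt9b (chromosome 11, 103727362 to 103775272) held 50 summits and Wnt3 (103774175 to 103818021) held 37, which is 1.04 and 0.844 per kb. The other 6 of the 8 protein-coding genes with the most summits per kb were from the same region, namely Mapt (0.915), which encodes the microtubule protein tau, Crhr1 (0.888), Map3k14 (0.882), Nsf (0.832), Plekhm1 (0.826) and Myl4 (0.825). All lay in a block from 103168102 to 105102177 with 1375 peaks (711 per Mb), 25 protein-coding genes and a median input background of 24.6 times the genome average. A second block, from 101806273 to 102041250, held 159 peaks (677 per Mb) at a background of 17.3 and included Meox1, Sost and Dusp3. Together the blocks held 1.97% of the peaks and 9.34% of the tags in peaks. Their median fold enrichment was 18.2, against 134 in the rest of the genome. Peaks with a fold of at least 30 numbered 143 per Mb in the blocks (exact 95% Poisson interval 127 to 160) and 29.1 per Mb elsewhere, but that limit kept 310 of the 1534 block peaks and 75949 of the 76179 others, so it removed most of the block peaks and few of the others. Set against the density within 500 kb on either side, Wnt9b had 50 summits where 36.7 were expected (exact conditional binomial test, p = 0.0475, adjusted p = 1 over 13890 genes and 0.380 adjusted over the list alone). Wnt3 had 37 where 34.0 were expected (exact p = 0.660, adjusted p = 1). The blocks and this test were defined after the data were seen. Without the peaks in the blocks, chromosome 11 was at 1.02 times its length share and no longer passed the exact test (adjusted p = 0.166).

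**Figure D3:**
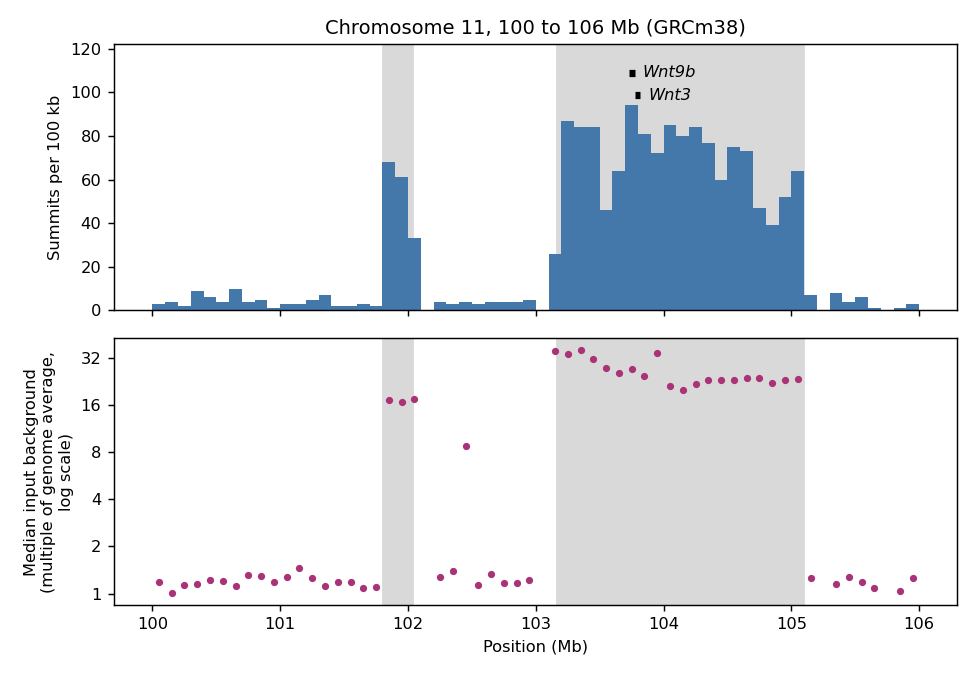
Summits per 100 kb (upper panel) and their median input background as a multiple of the genome average (lower panel, log axis) along the part of chromosome 11 that holds the 2 blocks (position in Mb), with the blocks shaded and black bars for Wnt9b and Wnt3. The blocks were defined by both quantities, and the Wnt genes lie within the larger block of 1375 peaks.

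Of the 19 Wnt ligands, 13 had a summit in the gene or within 5 kb of it, against 12.6 in lists of genes of the same length (exact stratified permutation, p = 1). Besides Wnt9b and Wnt3 these were Wnt5b with 6 summits in its span, Wnt11 with 5, Wnt7b with 4, Wnt4, Wnt5a, Wnt7a, Wnt9a and Wnt10b with 2 each, and Wnt3a, Wnt6 and Wnt10a with 1 each. Wnt11 had 5 summits where its flanks predicted 1.00 (exact p = 0.00901, adjusted p = 0.851 over all genes and 0.144 adjusted over the list alone). Clade B serpins, intracellular protease inhibitors clustered on chromosomes 1 and 13, had a summit at 16 of 27 members, against 15.9 expected (exact permutation p = 1), or 10.6 with matching on 5 bins of length and 4 of local density (adjusted p = 0.198). Serpinb2 had the peak with the highest p-score of the family (29 tags, fold 528), followed by Serpinb7 (16 tags, fold 258) and Serpinb8 (7 tags, fold 211). Serpinb6b had 4 summits where its flanks predicted 0.401 (exact p = 0.00240, adjusted p = 0.695 over all genes and 0.0552 adjusted over the list alone). Serpinb6a also had 4, with 2.04 expected, Serpinb5 and Serpinb10 had 2 each, and Serpinb1b, Serpinb1c, Serpinb6c, Serpinb9, Serpinb9c, Serpinb9d, Serpinb12 and Serpinb13 had 1 each in the span. Serpinb11 had a summit in its flank alone. None of the 16 Wnt ligands and 23 serpins long enough for the test passed it after adjustment over its list.

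Among all protein-coding genes, 13160 of 21887 (60.1%) had a summit in the gene or within 5 kb, and 3 of the 26 lists passed the test at an adjusted p under 0.05 (4 at an unadjusted p under 0.05). Vomeronasal receptors, the pheromone receptors of sensory neurons, had fewer peaks, at 56 of 353 members against 128 expected (exact permutation, adjusted p = 2.64e-21). Receptors within 20 kb of each other were also counted once, by the longest member of each cluster alone. Of these longest members, 47 had a peak against 115 expected (exact permutation, adjusted p = 3.30e-21). Peaks at the other members of a cluster were not counted. The members with the strongest peaks were Vmn1r228 (36 tags), Vmn2r92 (21 tags), Vmn2r6 and Vmn2r7 (18 tags each). Replication-dependent histones had more, at 23 of 63 against 12.5 (exact permutation, adjusted p = 0.0219), but these members shared 12 different summits. H2bc13, H2ac13 and H3c10 shared the same peak on chromosome 13, 21712797 to 21713104, and H2ac8 had another with 11 tags. Within the histone genes themselves, 2 members had a summit against 2.89 expected. With histone genes within 20 kb of each other counted once in the same way, 5 longest members had a peak against 2.80 expected (exact permutation, adjusted p = 0.757). Without matching on gene length the 23 members were fewer than the 37.9 expected (exact permutation, adjusted p = 0.00144). Fibroblast and endothelial markers had a summit at 26 of 28 members against 19.8 expected (exact permutation, adjusted p = 0.0363), led by Esam, Vwf, Tie1 and Col5a1 with strongest peaks of 41, 25, 23 and 22 tags. When lists were matched on the number of summits within 500 kb in 4 bins, with the length bins reduced from 20 to 5, the vomeronasal receptors still passed the exact permutation test (93.8 expected, adjusted p = 2.06e-06), while the histones (13.3 expected, adjusted p = 0.0604) and the fibroblast and endothelial markers (20.7 expected, adjusted p = 0.118) did not. In the exact permutation test the coarser length bins alone ended the call of the histones (18.1 expected, adjusted p = 0.680) and not that of the fibroblast and endothelial markers (19.7 expected, adjusted p = 0.0319). With 20 length bins and the same 4 density bins, the vomeronasal receptors (89.5 expected, adjusted p = 2.97e-05) and the histones (12.4 expected, adjusted p = 0.0116) passed the exact permutation test, and the fibroblast and endothelial markers did not (20.5 expected, adjusted p = 0.0820). Both of these binnings were chosen after the data were seen. Within 50 kb of the gene, 62 of the 63 histones had a summit against 42.2 expected (exact permutation, adjusted p = 2.08e-09). Windows of this width overlap between neighbouring histone genes, so few summits can serve many members. Clusters were not counted once here, and this p-value may be too small. With the 38912 peaks of higher p-score, the fibroblast and endothelial markers had 21 members with a peak against 15.2 expected and did not pass (exact permutation, adjusted p = 0.139).

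The other lists did not pass. KRAB-type and other Zfp zinc finger genes had a peak at 213 of 367 members (231 expected, exact permutation p = 0.0435, adjusted p = 0.282), and olfactory receptors at 238 of 1106 (254 expected). Genes of EMT and metastasis had one at 28 of 37 (26.5 expected), with Cdh2 (79 tags), Twist2, Zeb2 and Itga3 leading, and stemness genes at 26 of 38 (23.6), with Aldh1a1 (69 tags), Itgb3, Dand5 and Gli3. Itgb3 lies in the larger block on chromosome 11, and its strongest peak had a background of 25.9, against 1.19 for Aldh1a1. Hippo pathway genes had a peak at 22 of 33 (24.9), led by Stk3 with 128 tags, and Wnt receptors and signal transducers at 29 of 40 (28.7), led by Ror2 with 66 tags. Nuclear speckle and splicing factors, proteins of the bodies where Malat1 resides, had one at 28 of 42 (25.3), with Prpf8 (24 tags), Srsf4, Snrpa and Clk4, and paraspeckle proteins at 12 of 20 (13.2), with Hnrnpr (23 tags). Noncoding RNA genes had one at 16 of 35 (19.3), among them Pvt1 with 45 summits in its span and a background of 4.37 at its strongest peak. Among immune lists, inflammasome and pyroptosis genes had a peak at 20 of 31 (20.5), led by Aim2 with 134 tags, MHC class I antigen presentation at 14 of 20 (10.8), interferon response at 19 of 32 (18.3), and chemokines and cytokines at 19 of 33 (15.8). Cell cycle genes had a peak at 26 of 43 (25.5), led by Ccnd3 with 107 tags, cytosolic ribosomal proteins at 32 of 81 (29.1), housekeeping genes at 12 of 29 (14.7) and serpins of other clades at 12 of 31 (16.8). Markers of mammary epithelium had one at 26 of 37 (22.1), led by Erbb3 with 50 tags, T and NK cell markers at 16 of 32 (17.7), myeloid markers at 18 of 32 (16.2) and neuronal synaptic genes at 29 of 34 (29.7).

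**Figure D4:**
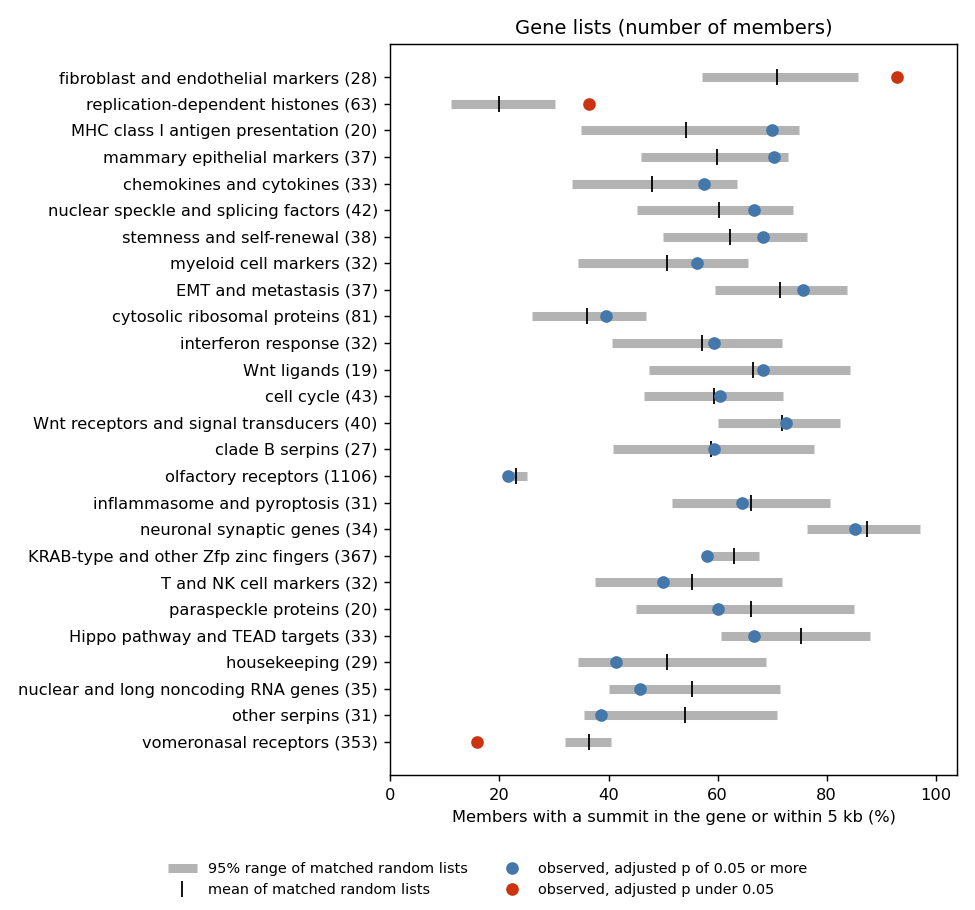
Percent of the members of each gene list (number of members in brackets) with a summit in the gene or within 5 kb, as points, against the mean (tick) and 95% range (grey bar) of random lists matched on gene length. The 3 lists in red had an adjusted p under 0.05, vomeronasal receptors to the left of their range and histones and fibroblast and endothelial markers to the right.

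Summits lay in and near genes more often than random positions did. These positions were drawn over whole chromosome spans with gaps kept, where no summit can lie, so the comparison may overstate the difference. Within 3 kb of either end of a protein-coding or lncRNA gene lay 16.3% of summits (95% Wilson interval 16 to 16.5), against 12.9% ± 0.120 (SD of 1000 random placements). Gene interiors held 45.1% against 39.8% ± 0.169, and intergenic sequence held 38.6% against 47.3% ± 0.174. Each p was 0.001998, two-sided, the smallest that 1000 placements can give. When each summit was instead moved by up to 500 kb, an alternative chosen after the data were seen, the random means were 15.3%, 44.3% and 40.4%, with the same p. Around the ends of the 6001 protein-coding genes of 40 kb or longer, the density was 38.5 summits per kb per 1000 ends inside the gene and 39.1 outside. At gene ends, 1 of the 26 lists passed: vomeronasal receptors had a summit at 29 of 353 members against 77.1 expected (exact permutation, adjusted p = 2.32e-11). Clade B serpins had 4 of 27 against 9.66 (exact permutation p = 0.0294, adjusted p = 0.248) and Wnt ligands 8 of 19 against 6.60 (p = 0.651, adjusted p = 0.870). Histones had 17 of 63 against 8.69 (exact permutation, adjusted p = 0.0785), with windows of 1 kb 5 against 4.19 (adjusted p = 1) and with windows of 10 kb 33 against 19.7 (adjusted p = 0.00571).

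**Figure D5:**
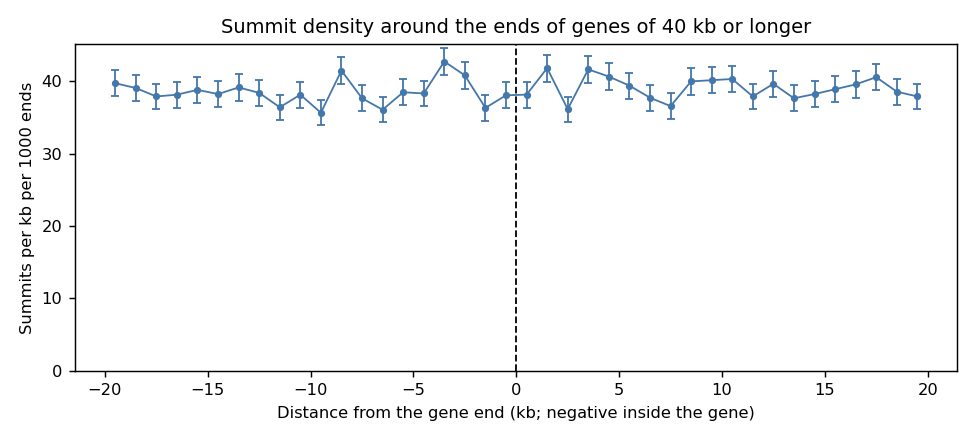
Summits per kb per 1000 gene ends (points, with Poisson standard errors) against distance from the end in kb, negative inside the gene, for the 6001 genes of 40 kb or longer. The means were 38.5 inside and 39.1 outside the gene.

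Because of the ceiling of height, the order of the highest folds says little about strength. The highest value lay on chromosome 6 at 79788120 to 79788677 (fold 1317, 102 tags), 29.6 kb from the nearest annotated gene, Gm20594. The next were in Il12rb1, a chain of the interleukin 12 receptor (fold 1263, 107 tags), at chromosome 14, 8901319 to 8901955 (fold 1257, 137 tags), in Tnni3k (fold 1257) and in Ccser2 (fold 1200). At gene ends the highest folds were at Obi1 (1197), AI467606 (1137), St8sia5 (1135), Gprc5c (1081), Olfr1508 (1077), D17H6S53E and Apom, which share a peak (970), Exoc7 (964), Cartpt (958), Gm3646 (933), Rcbtb2 (924) and Ticam1 (901). The highest p-score belonged to a peak at chromosome 2, 98666194 to 98667380, with a fold of 20.2 at a background of 65.3 times the genome average. Next in rank were the peak at chromosome 14, 8901319 to 8901955, and those in Aim2, in Clcn7 and at Malat1. All of these had a p-score of 3100, a value that 10 peaks share. The p-score therefore does not order these peaks, and its highest value says little about strength. Genes with the most summits in their span were Nsf (110), Gm11639 (105), Cntn5 (101), Mapt (94), Kirrel3 (91), Trappc9 (84), Kansl1 (82) and Ctnnd2 (74), of which Nsf, Gm11639, Mapt and Kansl1 lie in the larger block on chromosome 11. Against their flanks, 9 of 13890 genes had an adjusted p under 0.05. Sfi1 had 19 summits where 1.07 were expected, Mroh2a 25 against 3.04, Mtss1 50 against 12, Mpp3 21 against 4.41, Phactr3 24 against 4.83, Hnrnpul1 10 against 1.54 and Nav2 46 against 16.3. Tlk2, with 1 summit against 29.1, and Nmt1, with 0 against 13.3, had fewer and lie beside the larger block. The background within Sfi1 was 33.2 against 1.23 in its flanks, within Mroh2a it was 8.97 against 1.97, and within Mtss1 it was 6.78 against 2.48. No such rise was seen in Phactr3 (1.73 against 1.79), Hnrnpul1 (1.51 against 1.59) or Nav2 (1.35 against 1.31). Mpp3 (17.5 against 16.7) lies in the smaller block, which also supplies many of its flank peaks, so these values do not compare it with its surroundings outside the block. Sets of random intervals in place of the genes, drawn 100 times, gave a median of 6 calls (range 1 to 18).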

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

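Peaks outside the 20 compared chromosomes were flagged because they hold signal above input in sequence left out of the chromosome comparison. The 6 summits on the Y chromosome did enter the random placements and the gene list tests. The mitochondrial genome had 5 peaks with 3413 tags and folds of 13.1 to 30.9. The Y chromosome had 6 peaks with 127 tags, between 90739844 and 90812728. A total of 7 unplaced scaffolds had 96 peaks with 2099 tags, of which 65 peaks and 1742 tags lay on 1 scaffold, and a patch sequence had 3 peaks with 29 tags. Together these sequences held 0.852% of the tags in peaks. The median input background, as a multiple of the genome average, was 83.4 on the mitochondrial genome and 14.6 on Y. On the scaffolds it ran from 1.02 to 49.6 (18.4 on that with 65 peaks), and on the patch sequence it was 1.46. No lacZ value was at hand for any of these sequences.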

How the results depend on the processing

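The settings without the chromosome 11 blocks, with moved summits, with clusters of neighbouring members, with 5 length bins alone or 20 with local density, and every setting of the comparison with flanks were chosen after the data were seen. A cluster was counted by its longest member alone. A fold of at least 5 removes no peak, since the lowest is 6.66, so that setting tests nothing. Promoter, exon and intron shares and the GC-matched placement were not run. No paired analysis was possible because each group has 1 library and the peak list is merged.

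Gene-end, gene-interior and intergenic shares kept their direction and their side of the threshold except with the tenth of the peaks with the highest p-score and moved summits, at 16.3%, 44.5% and 39.2% (15.6%, 44.3% and 40.1% expected), where the differences were also smaller than with all peaks moved. Of the 26 lists in gene bodies, 3 passed; 2 did with the stricter 50% of peaks, 1 with the tenth, 6 without length matching, 1 with matching on local density and 5 length bins, 3 with 5 length bins alone (olfactory receptors in place of histones), 2 with local density and 20 length bins, 4 with windows of 50 kb, 2 with the gene body alone and 1 with clusters counted once, where fibroblast and endothelial markers stayed at 26 against 19.8 expected (exact permutation, adjusted p = 0.0545). Histones turned to fewer without length matching (23 against 37.9 expected), and passed with more at 17 against 7.32 expected with the stricter 50% of peaks (exact permutation, adjusted p = 0.00861). At gene ends 1 list passed; 2 did with the stricter 50% of peaks (histones with 14 against 4.98 expected, exact permutation, adjusted p = 0.00508), 0 with the tenth (0 also at an unadjusted p under 0.05 in the exact permutation test), 2 without length matching, 2 with 5 length bins alone (olfactory receptors added), 2 with local density and 20 length bins (histones with 17 against 8.03 expected, exact permutation, adjusted p = 0.0206) and 2 with windows of 10 kb. Wnt ligands and clade B serpins passed under none of the settings run. Against flanks, 9 genes passed; 8 did with flanks of 250 kb (6 of the 9 among them), 14 with flanks of 1000 kb (all 9 among them), 4 without the blocks, 5 with the stricter 50% of peaks, 1 with the tenth and 4 with peaks within 1 kb merged. Summits near Malat1 numbered 7 within 100 kb. The causes of these changes were not tested. Leaving out the fold setting, of 574 other list values 550 kept their side, as did 72 of 80 chromosome values. Most of these list values belong to lists that did not pass in the main setting, so they say little about the lists that passed. For named genes, the summits as a share of all peaks in the set stayed within the counting interval of the main share in 653 of 882 values.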

Other observations

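Gene families grouped by the root of their symbols, with at least 10 members, gave 281 tests, of which 4 passed, all with fewer peaks. Beside the vomeronasal receptors these were the Rhox homeobox genes of the X chromosome (0 of 33 with a peak, 14.5 expected, exact permutation, adjusted p = 6.97e-07), the Pramel genes (5 of 46, 22.7 expected, adjusted p = 1.15e-06) and the Skint genes (2 of 11, 9.02 expected, adjusted p = 1.10e-04). With matching on 5 length bins and 4 bins of summits within 500 kb, 1 of the 281 passed, and Rhox (6.15 expected, p = 0.00182, adjusted p = 0.256), Pramel (11.3 expected, p = 0.0223, adjusted p = 0.695) and Skint (6.76 expected, p = 0.00382, adjusted p = 0.268) did not pass the exact permutation test. With 5 length bins alone 6 passed, and with 20 length bins and the density bins 1 passed, so the coarser bins do not account for the fall. Whether sparse surroundings account for all of the 3 deficits is left open. All 33 Rhox genes lie on the X chromosome, which had 4.01 peaks per Mb, 0.135 times its length share. No matching was on chromosome, so the Rhox deficit cannot be told apart from that of the whole X chromosome. Neighbouring members, such as the 11 Skint genes, all on chromosome 4, were not counted once in these tests. This grouping and the added binnings were chosen after the data were seen.

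In what follows, the tests of dense bins, of local matching and of empty lengths were chosen after their results were seen, and those of tags per Mb and of the background floor before. Beyond added DNA copies and a preference of the pulldown, no biological explanation was tested, because the design gives no group in this merged list.

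Peaks were dense in parts of chromosome 11, which include Wnt9b and Wnt3, and uneven across chromosomes. More DNA copies of these regions in the cells may account for this: of bins of 100 kb with at least 20 peaks, chosen by peak number alone because the blocks were defined by their background, 57 of 58 (98.3%) had a median input background of at least 2, and 34 of the 35 outside the blocks did, against 609 of 5739 bins with 5 to 19 peaks (10.6%). Raised input depth does not tell added copies from other reasons for more input reads, such as reads of collapsed repeats. A preference of the pulldown beyond input depth was tested on 2167 autosomal windows outside the blocks. These had at least 10 peaks and a background above the floor, so they were chosen in part by their peaks. Across them, tags in peaks rose with background at a log-log slope of 1.95 (95% interval 1.86 to 2.04). The blocks, with 28630 tags per Mb, lay below the fitted line (61245) but within its 95% prediction interval (24943 to 150381). A value at or below the line was the outcome set in advance against a preference, and this outcome was met. The line was extrapolated to a background 3.37 times that of the highest window, so the result does not exclude a preference.

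Matching on local density did not remove the low number of vomeronasal receptors with a peak. With this matching, 93.8 would be expected in 5 length bins, and 89.5 in 20, against 56 observed. The density bins were few and wide, so density can still differ between genes within a bin. Whether sparse surroundings account for all of this deficit is therefore left open. Few placeable reads at near-identical copies may contribute. The share of peaks at the background floor within 500 kb of these genes was 15.8%, against 11.8% elsewhere on the same chromosomes, a ratio of 1.33 (95% interval 1.15 to 1.54). This lies between the bounds set in advance for and against that explanation and decides nothing.

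Among peaks of 3 tags, 16 of the 82 whole lengths from 55 to 136 bp held no peak, although the mean was 337 peaks per length. A candidate explanation is that the treatment tags were laid out at fixed steps along a coverage track instead of being sequenced reads. If so, tags are not independent counts, and the intervals and p-values of the caller would be too narrow.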
